A study of Mus musculus with 12 samples.

How the data were processed

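Tumour RNA from 12 samples, 6 from mice given PBS and 6 from mice given 100 µg of anti-CD4 antibody, was extracted, depleted of ribosomal and globin RNA and sequenced as 100-base read pairs on a NovaSeq instrument, per the labels' protocols. The submitters' processing notes list bcl2fastq 2.20.0.422, kallisto with no version and the genome build GRCm38.p6. The authors deposited estimated counts per gene symbol, as kallisto gives them, with 35.7% to 37.9% of the values in a tumour not whole. The annotation release, the step that summed transcripts to genes, the strand setting and any filter are not given in the sources used here. Because kallisto shares reads among similar transcripts, counts of paralogs, overlapping genes and antisense partners are uncertain where the text says so. The table holds 35999 gene symbols, of which 35973 matched GENCODE M21 on GRCm38, the source of all coordinates and gene types, and 26 had been turned into dates and carried 0.227% of the counts. The treatment label of each sample gave its group. The design text gives 6 mice per group, but no label ties a tumour to a mouse.

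Estimated counts were rounded to whole numbers and genes were kept by filterByExpr of edgeR 4.0.16 (R 4.3.3), which left 17940. Counts were scaled by TMM and tested with the edgeR quasi-likelihood F test with robust estimates, with no covariate, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. All adjusted p-values of genes come from this test unless another is named. The standard error of a log2 fold change was taken as its size over the square root of F and is approximate. The biological coefficient of variation was 0.193. On simulated counts with 17775 tested genes, the anti-CD4 against PBS comparison recovered 53% of genes changed 1.5-fold, 75.4% of those changed 2-fold and 98.4% of those changed 4-fold, and 5.77% of its calls were false. The simulation drew each gene independently, with no variation shared within a tumour beyond library size and group. These rates therefore need not hold for the real tumours.

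The design, the 34 gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. Lists were tested with camera of limma 3.58.1 (preset correlation 0.01), with an estimated correlation and with fry, which tests whether the members move on balance in the same direction without comparing them with other genes, and all were adjusted over the lists. A list score was the mean log2 CPM (prior count 2) of the tested members in each tumour, compared by an exact two-sided permutation test over all assignments of the 12 tumours and adjusted over the 34 lists. Shares of the library were compared in the same way over 6 classes. A count adjusted over the list alone repeats the adjustment among the members of that list. The rule named Cd4, Cd8a, Foxp3, Ifng, Gzmb, Tnf, Cd274 and Ptprc in any case, then the 10 genes that rose most and the 10 that fell most among called genes with a mean log2 CPM of 0 or more (leaving out receptor segments, pseudogenes and names that are only model numbers), and up to 4 members of each described list by smallest p together with its called members. Genes named outside that rule are Gm20716, Gm20388, Adnp, Dpm1, Cenpp, Cd3e, Msln, Ctla4, Klrg1, Vegfd, Sema3c, Sdc2, Esr1, Upk3b, Muc16, Cd79a, Cd79b, Ms4a1, Ighm, Pax5, Batf3, Xcr1, Tnfrsf9 and Lrrc32, chosen after their values were seen, and those of the lists written later. Ccdc22, also outside that rule, overlaps Foxp3, and the test of its reads was written before its values were seen.

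Tumours of the same group were compared for copies of a library, and chi-square per degree of freedom over genes was 8.01 to 61.1 for the 30 pairs, far above sampling noise. Totals ran from 30.75 to 62.06 M counts. Alternatives were RLE size factors, upper quartile scaling, DESeq2 1.42.0, limma voom with sample weights, no filter, a stricter filter (1 CPM in 6 tumours), a replicate block, library sizes without mitochondrially encoded, haemoglobin and receptor segment genes, a test against a fold of 1.2, and leaving out each tumour. Chosen after seeing the data were thinning to the lowest total, the log2 library total as a covariate, adipocyte and muscle scores as covariates, and leaving out both anti-CD4 3 and 4. 8 further lists (plasmacytoid, mature and type 1 conventional dendritic cells, small leucine-rich proteoglycans, caveolae and GIMAP GTPases) were written after the first results had been seen.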

Results

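RNA was sequenced from subcutaneous tumours of AB1-HA, a transplantable mouse mesothelioma line that carries influenza haemagglutinin as a marker antigen. The tumours grew in male BALB/c mice that received PBS or 100 µg of an anti-CD4 antibody, which removes CD4 T cells, on days -3, 0 and 7 relative to tumour inoculation. Tumours were taken on day 9, with 6 tumours in the PBS group and 6 in the anti-CD4 group. Each tumour gave an estimated count per gene for 35999 gene names, and 17940 genes had enough counts to be tested. Total counts of PBS tumours 1 to 6 were 41.93, 35.56, 39.1, 30.75, 33.08 and 36.07 M, and those of anti-CD4 tumours 1 to 6 were 34.45, 43.44, 37.9, 51.81, 48.72 and 62.06 M. The anti-CD4 libraries were deeper, at 46.4 ± 10.04 M against 36.08 ± 4.03 M (SD, n = 6 each, exact permutation p = 0.039).

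The comparison asked how tumours of mice depleted of CD4 T cells differ from tumours of mice with CD4 T cells in place. Cd4, which encodes the antigen bound by the antibody and lies on chromosome 6 from 124864692 to 124888221 in GRCm38, fell to 20.8% of its PBS level. Its normalised level was 6.31 ± 2.34 CPM in PBS tumours and 1.31 ± 0.50 CPM in anti-CD4 tumours (SD, n = 6 each). Every anti-CD4 tumour, at 0.618 to 2.13 CPM, lay below every PBS tumour, at 4.35 to 9.93 CPM. The exact two-sided permutation p of 0.00216 is the smallest this design can give. In the edgeR fit the log2 fold change of Cd4 was -2.26 (SE 0.28, adjusted p = 0.00298).

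**Figure D1:**
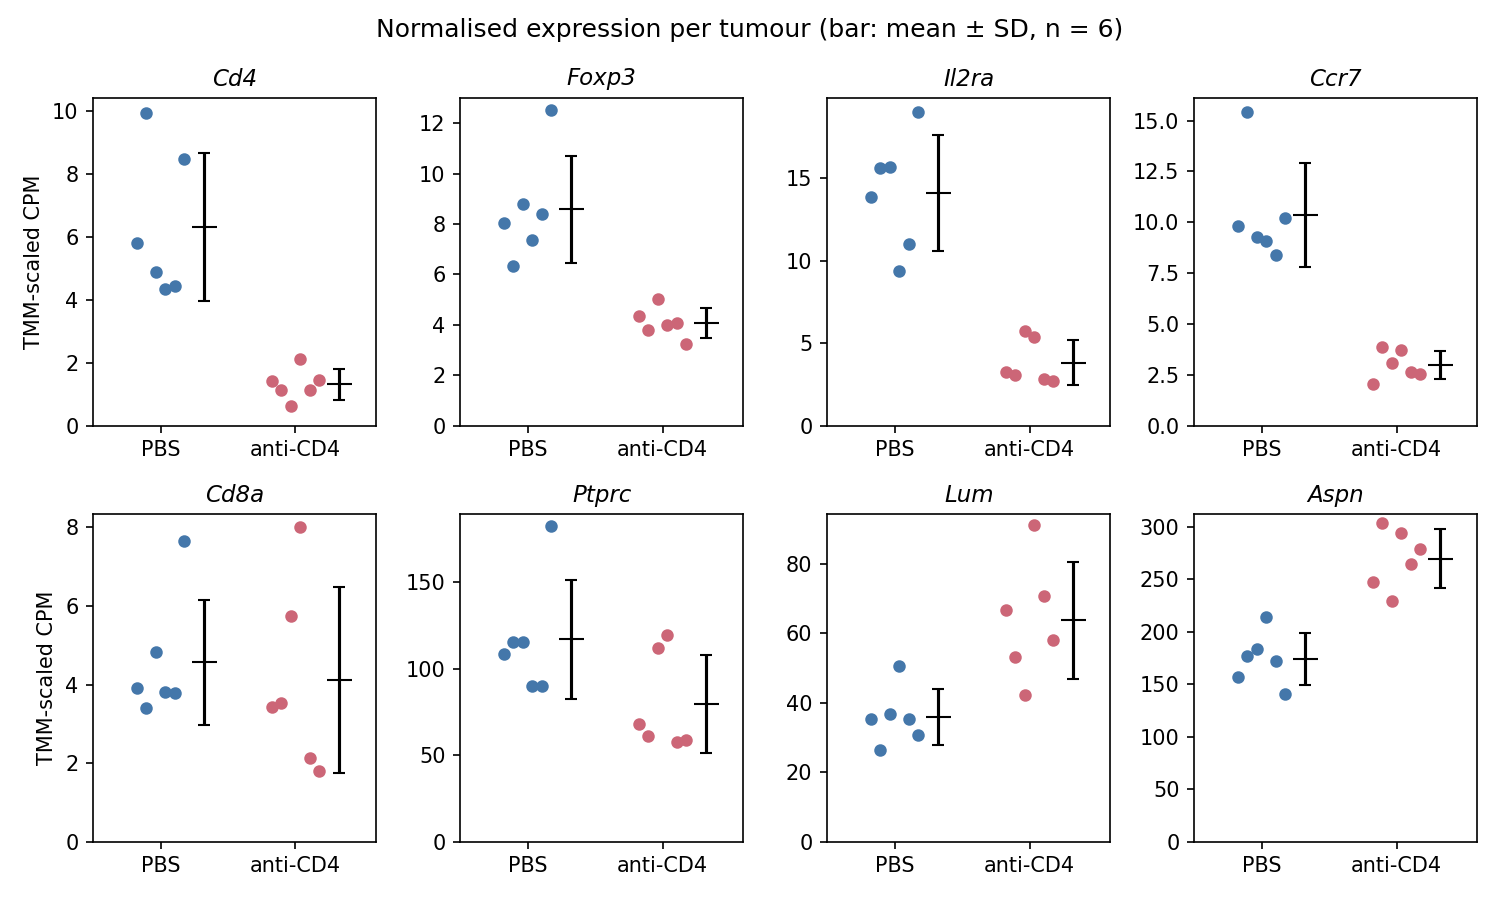
TMM-scaled CPM (vertical axes, linear, from 0) of 8 genes in 6 PBS tumours (blue points) and 6 anti-CD4 tumours (red points), with the group mean ± SD beside the points. Cd4, Foxp3, Il2ra and Ccr7 are lower in every anti-CD4 tumour than in any PBS tumour and Aspn is higher in every one, while the groups overlap for Cd8a, Ptprc and Lum.

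List scores of pan, CD4 helper, regulatory and naive T cells fell in the anti-CD4 tumours (exact permutation). Those of NK cells, dendritic cells, B cells and antigen presentation by MHC class II fell as well. The CD8 T cell score did not pass, and camera with an estimated correlation called only the regulatory T cell list. The genes that rose did so by less and included genes of connective tissue. Of the 17940 genes, 418 fell, with a median log2 fold change of -0.72, and 529 rose, with a median of 0.26. A change of at least 2-fold was reached by 124 of the genes that fell and by 1 that rose. That gene, chosen after its value was seen, was Gm20716, a gene model on chromosome 2 from 168180986 to 168230364 that spans Adnp and Dpm1 on the same strand, so its count is uncertain (log2 fold change 2.48, SE 0.49, adjusted p = 0.0271). The genes that fell most under the naming rule were Car4, a carbonic anhydrase (log2 fold change -2.73, SE 0.53), Cd4, Icos, a costimulatory receptor of activated T cells (-2.25), Cd5, a T cell surface receptor (-2.18), and Ramp3, an accessory protein of the calcitonin receptor family (-2.13). Arg1, the arginase of myeloid cells (-2.13), Slain1 (-1.95), Tnfrsf4, the OX40 receptor (-1.91), Il2ra, the alpha chain of the interleukin 2 receptor (-1.89), and Il12b, the p40 chain of interleukin 12 (-1.81), followed. All 10 were lower in every anti-CD4 tumour than in any PBS tumour.

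The count of calls depended on single tumours, and 694 of the 947 had an adjusted p of 0.03 or more. Higher and lower calls numbered 29 and 33 without anti-CD4 2, 35 and 31 without anti-CD4 5, 54 and 36 without anti-CD4 6, 67 and 94 without PBS 3, 91 and 65 without PBS 6, 99 and 153 without PBS 5, and 120 and 119 without PBS 2. They numbered 1160 and 1480 without PBS 1, 1044 and 1153 without anti-CD4 1, 320 and 369 without anti-CD4 3 alone, 295 and 358 without anti-CD4 4 alone, and 479 and 291 without PBS 4. With the log2 library total as a covariate, 0 genes were higher and 5 lower in edgeR, namely Cd4 (-2.55), Cd5 (-2.29), Ccr7 (-1.87), Il12b (-1.79) and Ramp3 (-2.17), with 2193 genes at an unadjusted p under 0.05 in that fit and 5027 without the covariate. The share of calls that were higher was 55.9% with TMM scaling and 35.5% with upper quartile scaling. In all 12 fits that leave out a tumour, 25 lower and 26 higher genes kept their call, among them Cd4, Cd5, Foxp3, Il2ra, Ccr8, Izumo1r, Tnfrsf4, Ccr7, Ccl22, Il12b, Flt3, Aspn and Ogn. Every other gene described here as having risen or fallen lost its call in at least 1 of these fits, apart from Ramp3, Ikzf2, Ikzf4, Gm20388, Klrg1, Bcl2l14, Cav2, Cavin2, Vegfd, Sema3c, Sdc2 and Esr1.

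**Figure D2:**
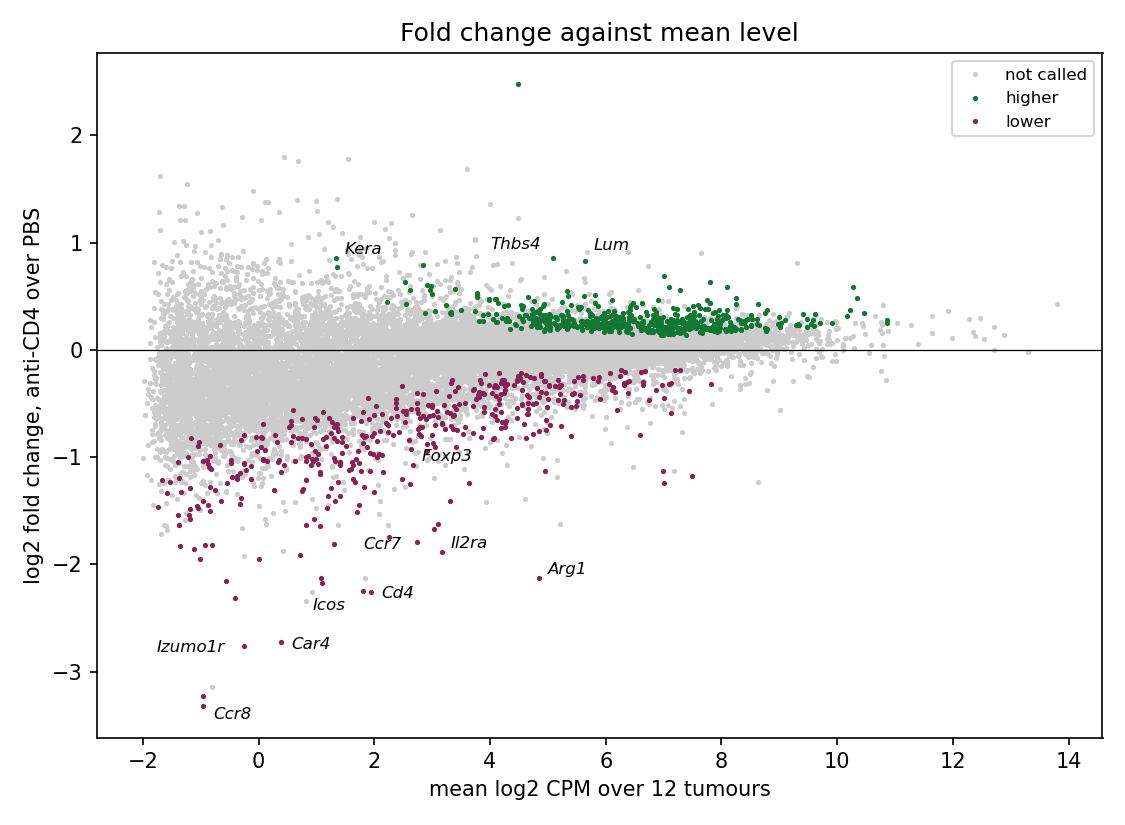
Log2 fold change of anti-CD4 over PBS (vertical axis) against mean log2 CPM over the 12 tumours (horizontal axis) for the 17940 tested genes, with 529 genes that rose in green, 418 that fell in purple and genes that did not pass in grey. The falls reach further than the rises, and Ccr8, Izumo1r and Car4 lie lowest among the labelled genes.

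With all 12 tumours, the regulatory T cell list had the lowest score difference of the 34 lists fixed beforehand. That order depended on anti-CD4 3 and 4, since without both the pan T cell (-1.75) and NK cell (-1.69) differences were lower than that of regulatory T cells (-1.63), and without anti-CD4 3 alone that of NK cells was lower. Of 11 tested members of this list, 9 fell, with the same 9 adjusted over the list alone, and the list median was -1.62. Ccr8, a chemokine receptor of tumour regulatory T cells, fell by 3.32 on the log2 scale (SE 0.43), from a mean of 0.88 to 0.085 CPM. Izumo1r, the folate receptor 4 gene, fell by 2.76 (SE 0.35), from a mean of 1.42 to 0.21 CPM. Both lay below the mean log2 CPM of 0 asked of the genes ranked by fold change. Ikzf2 and Ikzf4, which encode the transcription factors Helios and Eos, fell by 1.62 and 1.64. Tnfrsf18, the GITR receptor, fell by 0.80, and Gpr83 fell too. Foxp3, the lineage factor on chromosome X from 7573644 to 7595245, fell from 8.58 ± 2.12 to 4.08 ± 0.60 CPM (SD, n = 6 each), a log2 fold change of -1.08 (SE 0.16, edgeR adjusted p = 0.00705). Its 3' end overlaps Ccdc22 on the opposite strand over 1437 bases, and whether the counting used strand is not given in the sources used here, so part of the Foxp3 count may belong to Ccdc22. Ctla4 was too low to be tested, with 24.1 summed counts in the PBS tumours and 0.108 in the anti-CD4 tumours. The list score, the mean log2 CPM of the members, fell by 1.43 (exact permutation p = 0.00216, adjusted p = 0.0147). It was the only 1 of these 34 lists that camera called with an estimated correlation (adjusted p = 0.0468). With the library total as a covariate the score difference was -1.35 (SE 0.22).

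The broader T cell lists were lower as well. Of 20 tested pan T cell genes, 4 fell and 17 were lower adjusted over the list alone, with a median of -1.06. They were Cd5, Cd2, an adhesion receptor (-1.64), Zap70, a kinase of T cell receptor signalling (-1.47), and Ubash3a, a phosphatase of the same pathway (-0.61). The Cd3 chains did not pass, with Cd3e at -1.28 (SE 0.50, adjusted p = 0.128). The list score fell by 1.30 (exact permutation p = 0.00649, adjusted p = 0.0315), and camera gave an adjusted p = 0.26 with an estimated correlation. Of 9 CD4 helper genes, 2 fell, Cd4 and Icos, also 2 adjusted over the list alone. The score fell by 0.70 (exact permutation, adjusted p = 0.0147), with camera at adjusted p = 0.124 with an estimated correlation. The list median was -0.346, and Cd4, the antigen of the antibody, is itself a member. Of 9 genes of naive and lymph node homing T cells, 3 fell, and 6 were lower adjusted over the list alone. These were Ccr7, the homing receptor of T cells and migrating dendritic cells (-1.79, SE 0.18), Il7r, the interleukin 7 receptor (-1.21), and Ccr9, a homing receptor whose locus overlaps several other genes (-0.67). This score fell by 0.745 (exact permutation, adjusted p = 0.0147), with camera at adjusted p = 0.124 with an estimated correlation.

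Cd8a, the alpha chain of CD8, did not pass the test, at 4.57 ± 1.58 CPM in PBS and 4.11 ± 2.36 CPM in anti-CD4 tumours (SD, n = 6 each; log2 fold change -0.15, SE 0.34, edgeR adjusted p = 0.794). None of 7 tested CD8 T cell genes changed and 1 was lower adjusted over the list alone. The score differed by -0.76 (exact permutation p = 0.0823, adjusted p = 0.147), and camera, which called the list lower, gave an adjusted p = 0.463 with an estimated correlation. Of 12 cytotoxic effector genes, 2 fell, Ctsw, a protease of cytotoxic lymphocytes (-0.996), and Ccl5, a chemokine (-0.78), and 5 were lower adjusted over the list alone. Ifng had a log2 fold change of -1.71 (SE 0.62, adjusted p = 0.099) and Gzmb, a granzyme of the same cells, one of -0.90 (SE 0.56, adjusted p = 0.31), so neither passed. The cytotoxic score differed by -1.09 (exact permutation p = 0.0303, adjusted p = 0.0793). Camera called the cytotoxic list lower with its preset correlation (adjusted p = 1.43e-05) but not with an estimated correlation (adjusted p = 0.357). Anti-CD4 3 and 4 had cytotoxic scores of 1.13 and 1.10, against -0.96 to -0.14 in the other anti-CD4 tumours, which lay below every PBS tumour (0.54 to 1.99). Of 8 NK cell genes, 1 fell, Klre1 (-1.14), and 7 were lower adjusted over the list alone. The NK score fell by 1.27 (exact permutation, adjusted p = 0.0401), with camera at adjusted p = 0.26 with an estimated correlation. Of 11 checkpoint genes, 3 fell, Tigit (-0.60), Lag3 (-0.76) and Cd244a (-0.95), all inhibitory or regulatory receptors of lymphocytes, and 7 were lower adjusted over the list alone. That score fell by 0.58 (exact permutation, adjusted p = 0.0327; camera adjusted p = 0.26 with an estimated correlation).

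The scores of the dendritic cell, costimulation, MHC class II and B cell lists fell as well (exact permutation), while most of their genes did not pass singly. Of 15 dendritic cell genes, 5 fell and 9 were lower adjusted over the list alone. Ccl22, a chemokine that attracts regulatory T cells, fell by 1.67 (SE 0.22), Siglech, a surface lectin of plasmacytoid dendritic cells, by 1.41, Flt3, the receptor for the dendritic cell growth factor, by 0.80, and Zbtb46, a transcription factor of conventional dendritic cells, by 0.69. Irf8, a transcription factor of dendritic cells, fell by 0.80, but the gene model Gm20388 spans it on the same strand and rose by 0.68, so the split of reads between them is uncertain. The score fell by 0.63 (exact permutation, adjusted p = 0.0147; camera adjusted p = 0.154 with an estimated correlation). Of 11 genes of costimulation and CD40 licensing, 4 fell, Ccr7, Il12b, Cd40, the receptor for CD40 ligand (-0.74), and Traf1, a signalling adaptor (-0.34). In this list 6 were lower adjusted over the list alone, and the score fell by 0.56 (exact permutation, adjusted p = 0.0147; camera adjusted p = 0.124 with an estimated correlation). Of 11 MHC class II genes, 2 fell, H2-Eb1 (-1.24) and H2-Aa (-1.17), both chains of class II molecules, and 10 were lower adjusted over the list alone. The class II score fell by 0.95 (exact permutation, adjusted p = 0.0368; camera adjusted p = 0.26 with an estimated correlation). Of 13 B cell genes, 3 fell, Cd22 (-0.81), Spib (-1.04) and Blk (-1.63), and adjusted over the list alone 4 were lower and 1 higher. Spib and Blk are also genes of plasmacytoid dendritic cells, and Cd79a (-0.01, adjusted p = 0.978), Ms4a1 (-0.40, adjusted p = 0.287) and Pax5 (0.19, adjusted p = 0.621) did not pass. The B cell score fell by 0.43 (exact permutation, adjusted p = 0.0315; camera adjusted p = 0.36 with an estimated correlation).

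**Figure D3:**
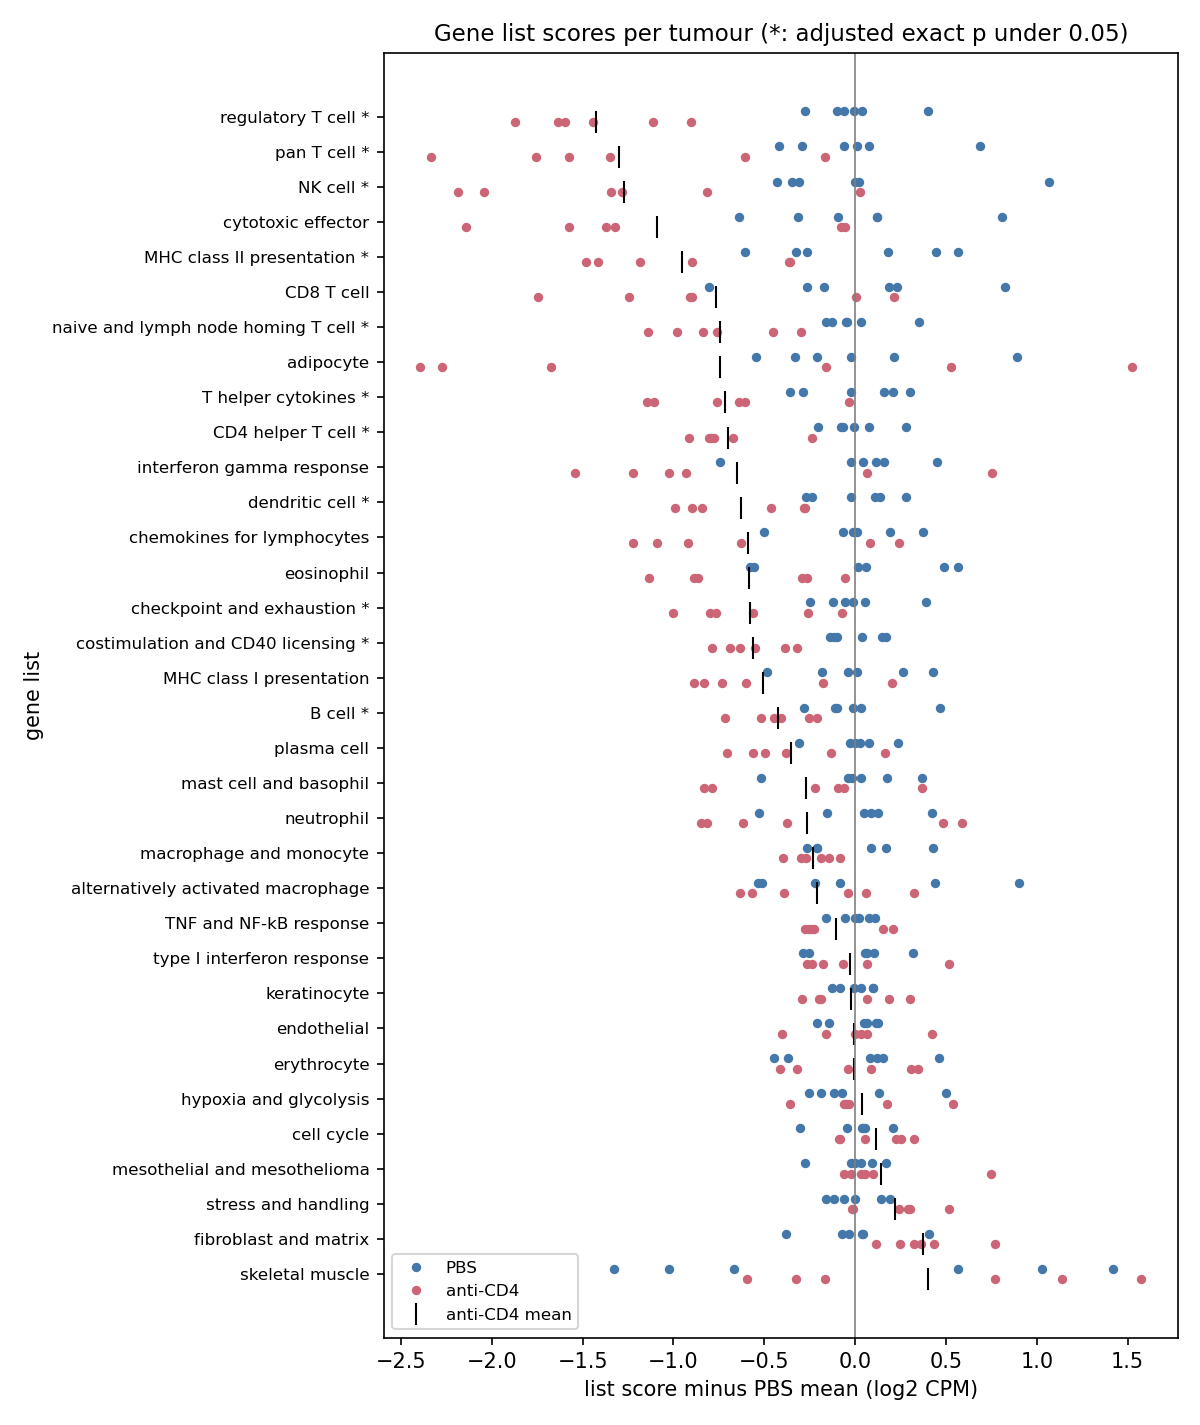
Score of each of 34 gene lists per tumour as the difference from the PBS mean (horizontal axis, log2 CPM), with lists on the vertical axis, PBS tumours in blue, anti-CD4 tumours in red, a black bar at the anti-CD4 mean and an asterisk at the 11 lists whose exact permutation test passed after adjustment. The regulatory T cell, pan T cell and NK cell scores lie lowest, and the adipocyte and skeletal muscle scores spread widely within both groups.

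Among the other immune lists, the T helper cytokine score fell and the other scores did not pass. Camera with its preset correlation did call the macrophage and monocyte list lower (adjusted p = 0.00988). It also called lower the interferon gamma (adjusted p = 0.000103), MHC class I (1.43e-05), T helper cytokine (0.0156) and lymphocyte chemokine (0.00325) lists. Ptprc, which encodes the leukocyte marker CD45, was at 117 ± 34.2 CPM in PBS and 79.7 ± 28.3 CPM in anti-CD4 tumours (SD, n = 6 each; log2 fold change -0.55, SE 0.24, edgeR adjusted p = 0.161). None of 20 macrophage and monocyte genes changed, also 0 adjusted over the list alone, and the score differed by -0.23 (exact permutation, adjusted p = 0.155; camera adjusted p = 0.505 with an estimated correlation). Arg1 was the 1 of 13 genes of alternatively activated macrophages to fall, also 1 adjusted over the list alone (score -0.21, exact permutation, adjusted p = 0.594), and the PBS tumours varied widely in it, at 47.0 ± 38.7 CPM against 10.8 ± 4.58 CPM. Of 25 genes of the interferon gamma response, all 25 had negative log2 fold changes and 1, Irf8, fell, also 1 adjusted over the list alone. Anti-CD4 3 had an interferon gamma score of 5.65, above every PBS tumour (4.16 to 5.35), anti-CD4 4 one of 4.96, and the other anti-CD4 tumours 3.36 to 3.97, below every PBS tumour. That score differed by -0.65 (exact permutation, adjusted p = 0.221; camera adjusted p = 0.552 with an estimated correlation), and its member Cd274, the PD-L1 gene, did not pass (-0.53, SE 0.44, adjusted p = 0.447). Of 18 MHC class I genes, 1 fell, H2-Q7 (-1.13), also 1 adjusted over the list alone, and the score differed by -0.505 (exact permutation, adjusted p = 0.108; camera adjusted p = 0.463 with an estimated correlation). Of 15 T helper cytokine genes, only 7 had enough counts to be tested, so the score leaves out most of the list. Of these 7, 0 changed and 3 were lower adjusted over the list alone. The score fell by 0.715 (exact permutation, adjusted p = 0.0327), with camera at adjusted p = 0.26 with an estimated correlation. Tnf, a tested member of this list, was at -0.61 (SE 0.20, edgeR adjusted p = 0.0805). Of 14 lymphocyte chemokines, 3 fell, Ccl22, Ccl5 and Cxcl16 (-0.56), also 3 adjusted over the list alone (score -0.59, exact permutation, adjusted p = 0.127; camera adjusted p = 0.36 with an estimated correlation). Traf1 was the 1 of 21 genes of the TNF and NF-kB response to fall, also 1 adjusted over the list alone, and camera called the list lower (adjusted p = 0.044; adjusted p = 0.633 with an estimated correlation). The type I interferon, plasma cell, neutrophil, mast cell and basophil, and eosinophil lists had no changed gene and passed neither camera nor the score test, with score differences of -0.03, -0.35, -0.26, -0.27 and -0.58.

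Connective tissue genes lay in the other direction. Of 21 fibroblast and matrix genes, all had positive log2 fold changes, 3 rose and 12 were higher adjusted over the list alone. Lum, the proteoglycan lumican, rose from 35.9 ± 8.11 to 63.7 ± 16.7 CPM (SD, n = 6 each; log2 fold change 0.83, SE 0.18), Sparc, a collagen-binding matrix protein, rose by 0.37 (SE 0.09), and Pdgfra, a growth factor receptor of fibroblasts, by 0.28 (SE 0.07). The score differed by 0.375 (exact permutation p = 0.0216, adjusted p = 0.0613), and the camera call was lost at adjusted p = 0.26 with an estimated correlation. The genes that rose most under the naming rule were the proteoglycan Kera (0.86), Thbs4, a matrix thrombospondin (0.86), Lum, Sfrp1, a secreted Wnt antagonist (0.79), Cyp2c55, a cytochrome P450 (0.77), and Aspn, a small proteoglycan (0.63). Slc38a4, an amino acid transporter (0.61), Akr1c14, a hydroxysteroid dehydrogenase (0.59), Cav1, the caveolin of caveolae (0.59), and Ogn, another small proteoglycan (0.59), followed. Aspn and Ogn lie on chromosome 13 from 49544443 to 49567565 and from 49608046 to 49624501, within Cenpp on the opposite strand, which did not pass (Cenpp 0.12, adjusted p = 0.385).

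Lists of tumour and tissue cells showed few changed genes. Pdpn, which encodes podoplanin, was the 1 of 7 mesothelial genes to rise (0.33, SE 0.06), also 1 adjusted over the list alone, and Msln, the mesothelin gene, did not pass (-0.04, adjusted p = 0.866). None of 26 cell cycle genes passed, although 24 had positive values and camera called the list higher (adjusted p = 0.00679; adjusted p = 0.695 with an estimated correlation). With the library total as a covariate its direction turned to lower (camera adjusted p = 0.345). Of 14 stress and handling genes, 0 passed and camera called the list higher (adjusted p = 0.00988; adjusted p = 0.376 with an estimated correlation), with a score difference of 0.22 (exact permutation, adjusted p = 0.126). The endothelial list had 0 of 15 genes changed and a score difference of -0.01 (exact permutation, adjusted p = 0.981), although camera called it lower with the library total as a covariate (adjusted p = 0.0145). The skeletal muscle, adipocyte, hypoxia and glycolysis, keratinocyte and erythrocyte lists had no changed gene and passed neither test, with score differences of 0.40, -0.74, 0.04, -0.02 and -0.01. Median, mean and test differed in sign for the adipocyte, endothelial, erythrocyte, keratinocyte and type I interferon lists. Muscle and fat genes differed between tumours of the same group, with muscle scores of 4.18 ± 1.2 in PBS and 4.58 ± 0.88 in anti-CD4 tumours and adipocyte scores of 3.92 ± 0.51 and 3.18 ± 1.6 (SD, n = 6 each), and with both scores as covariates 30 genes were higher and 29 lower.

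Over all 34 lists, camera with its preset correlation called 18 lower and 3 higher, while 11 list scores fell and 0 rose. With an estimated correlation camera called 1 lower and 0 higher. With PBS 6 left out 4 list scores were lower, those of CD4 helper, regulatory, and naive and homing T cells and of costimulation, which also passed in the other fits without 1 tumour. The dendritic cell and B cell scores lost their call without PBS 6 alone, and the pan T cell score without PBS 1, 2, 3 or 6. The checkpoint and T helper cytokine scores lost it without any 1 of these 4 or anti-CD4 6, and the NK cell and MHC class II scores without any 1 of these 4 or anti-CD4 1, 2, 5 or 6. Where a call was lost, the adjusted p was 0.0515 to 0.0736 (exact permutation) and the difference stayed negative. It was -1.31 to -1.16 for pan T cells, -1.33 to -1.06 for NK cells and -1.01 to -0.831 for MHC class II. Without PBS 6 it was -0.568 for dendritic cells and -0.331 for B cells. With PBS 1, 2 or 3 left out 6 list scores were lower. Of 6 classes of transcript, T cell receptor segments took a smaller share of the library in anti-CD4 tumours, 0.000772% ± 0.00045 against 0.00188% ± 0.00072 (SD, n = 6 each, exact permutation p = 0.00649, adjusted p = 0.039). This call was lost without PBS 1, 2, 3, 5 or 6 and without anti-CD4 1, 2, 3, 5 or 6, each left out alone, with the T cell receptor segment share at adjusted p of 0.0519 to 0.0909 by exact permutation. The shares of mitochondrially encoded genes (1.84% against 1.99%), ribosomal protein genes (2.03% against 1.93%), immunoglobulin segments (0.00117% against 0.00171%), haemoglobin genes (0.00012% against 0.000126%) and the 10 highest genes (7.48% against 6.98%) did not differ by more than the spread between tumours.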

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

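The test of list scores against other splits was chosen only after the split count of the camera lists had been seen. Of 98 groups of tumours checked for a tumour far from the others of its group, 7 held such a tumour, where chance, which marks about 1 in 20 groups, gives about 4.9. PBS 6 had an NK cell score of 2.12, with the next at 1.071, a T cell receptor segment share of 0.003295%, with the next at 0.001888%, a Cd8a level of 7.647 CPM, with the next at 4.839 CPM, and a Ptprc level of 182.7 CPM, with the next at 115.3 CPM. Anti-CD4 4 had a CD4 helper T cell score of 2.841, above the others at 2.163 to 2.406. In the same tumour the 10 highest genes took 7.866% of the counts, against 7.323% to 7.523% in the other anti-CD4 tumours. Anti-CD4 6 had a mesothelial score of 2.457, with the next at 1.809, and held 112 counts of Upk3b and 170 of Muc16, genes of mesothelium, where the other anti-CD4 tumours held at most 19 of each.

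Chance is unlikely to account for the number of genes called. Of 100 splits of the 12 tumours, 1, the real one with 947 genes, gave as many, and the highest other split gave 149. Chance is also unlikely to account for the 11 list scores that fell, since 4 of all 462 splits gave as many. The highest other split gave 15, however, and this count was added later. Chance remains open for the 21 lists called by camera with its preset correlation, since 13 of 100 splits gave as many and the highest other gave 26.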

How the results depend on the processing

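Thinning, the library total covariate, the adipocyte and muscle covariates and leaving out both anti-CD4 3 and 4 were chosen after seeing the data, and the cause of the changes below was not tested except where named. Cd4 kept its direction and its exact p of 0.00216 under RLE scaling (-2.26), the plain library total (-2.35) and in each fit without 1 tumour, with a log2 ratio of group means of -2.46 to -2.09 over those fits, and was -2.30 without both anti-CD4 3 and 4 (exact permutation p = 0.00476). Against 529 higher and 418 lower genes, RLE factors gave 583 and 421, thinning 493 and 400, the stricter filter 504 and 426, and leaving out transcript classes 436 and 438. Upper quartile scaling gave 179 higher and 325 lower, no filter 272 and 251 (27373 genes tested), DESeq2 1345 and 1180, voom with sample weights 2848 and 3200, the library total covariate 0 and 5 in edgeR (2193 at an unadjusted p under 0.05), and the adipocyte and muscle covariates 30 and 29. The test against a fold of 1.2 gave 0 higher and 16 lower in edgeR (1590 at an unadjusted p under 0.05), since it asks for larger changes. Without both anti-CD4 3 and 4, picked for their high scores, a choice that itself favours falls, 378 genes were higher and 705 lower, 18 list scores were lower, and the type I interferon list reversed to lower (adjusted p = 0.0281). Leaving out 1 tumour gave 29 to 1160 higher and 31 to 1480 lower genes, 2 to 4 higher and 14 to 19 lower lists, 0 to 1 higher and 4 to 14 lower list scores, and 0 to 2 called shares. The estimated correlation gave 0 higher and 1 lower list, fry 1 higher and 12 lower, and z-scores 1 higher and 10 lower list scores. Without mitochondrially encoded and haemoglobin genes 2 shares were called. With the library total as a covariate the cell cycle list (adjusted p = 0.345) and the endothelial list (adjusted p = 0.0145) reversed to lower. The replicate block gave 19 higher and 14 lower genes, but the labels do not say that the numbers pair the tumours. Same-number correlations ran from -0.41 to 0.23, and 0 PBS tumours were closest to their own number, which shows no pairing but cannot exclude it. Of values that passed in either setting, 0 others reversed, while Cd8a, which did not pass in any fit without 1 tumour, ran from -0.462 to 0.0554. Depth limits genes such as Ctla4, which was too low to test.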

Other observations

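Further gene lists, written after the first results had been seen and in part drawn from the fixed lists, moved with the anti-CD4 antibody. Of 8 tested genes of the GIMAP GTPases, a lymphocyte family, 4 fell, Gimap3 (-1.74), Gimap5 (-0.99), Gimap1 (-0.82) and Gimap6 (-0.51), and the score fell by 0.88 (exact permutation, adjusted p = 0.0104; camera adjusted p = 0.0915 with an estimated correlation). Klrg1, an inhibitory receptor of effector lymphocytes, fell by 3.23 (SE 0.44, edgeR adjusted p = 0.00386), and Bcl2l14, a member of the Bcl2 family, fell by 2.31 (SE 0.34). Of 6 genes of type 1 conventional dendritic cells, all had negative values and 0 passed, Batf3 (-1.10, adjusted p = 0.0715) and Xcr1 (-0.44, adjusted p = 0.199) among them. Their score fell by 0.57 (exact permutation, adjusted p = 0.0152; camera adjusted p = 0.116 with an estimated correlation), but all 6 come from the fixed dendritic cell list, whose fall had been seen, so this is not independent evidence.

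Among genes of connective tissue, 4 of 11 small leucine-rich proteoglycans rose, Kera, Lum, Aspn and Ogn, and the list score rose by 0.49 (exact permutation, adjusted p = 0.0115). Dcn, the decorin gene, was at 0.92 (SE 0.27, adjusted p = 0.0636), and Bgn, the biglycan gene, at 0.05 (adjusted p = 0.749). Of 5 caveola genes, 4 rose, Cav1 (0.59), Cav2 (0.56), Cavin2 (0.40) and Cavin3 (0.34), and their score rose by 0.44 (exact permutation, adjusted p = 0.00433). Both lists hold genes picked from these libraries, so their direction is not independent evidence. Other genes higher in every fit without 1 tumour were Vegfd, a lymphangiogenic growth factor (0.49), Sema3c, a semaphorin (0.44), Sdc2, a syndecan (0.39), and Esr1, the oestrogen receptor (0.32).

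The tests of equal leukocyte loss, lymph node tissue, dilution, read depth, the library total and transcript ratios were chosen only after the results were seen, while those of Ccdc22 reads and of dendritic cells were written before their own values, though after the patterns, had been seen. Regulatory T cell genes fell further than macrophage genes, and the difference of their scores was -1.2 (exact permutation p = 0.00216). Both scores were known when this test was chosen, so the value restates them. The 2 lists did not fall alike, but an equal loss of all leukocytes stays open. It would lower both scores alike only if leukocytes alone gave these transcripts, which was not tested. Cd79a, Cd79b, Ms4a1 and Ighm, B cell genes abundant in lymph node, were used to ask about lymph node tissue in the PBS tumours. The regulatory T cell score fell by 1.17 more than theirs (exact permutation p = 0.00216), which argues against such tissue as the whole cause. It cannot exclude such tissue as a part, since a loss of CD4 T cells would give the same difference. The score of the fixed B cell list fell by 0.43. A loss of regulatory T cells together with other CD4 T cells under the antibody remains a candidate explanation from the design, and these bulk values cannot separate fewer cells from fewer transcripts per cell.

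Matrix genes were higher with anti-CD4, by 0.375 (SE 0.14) in the list score, although the score test did not pass after adjustment (exact permutation, adjusted p = 0.0613). Dilution by fewer leukocytes would raise endothelial genes as well, but the matrix score minus the endothelial score was 0.382 higher (exact permutation p = 0.00866). The endothelial list was picked with both scores known, so this value restates them. Other tissue lists differed in score by 0.40 (skeletal muscle), 0.14 (mesothelial), -0.01 (erythrocyte), -0.02 (keratinocyte) and -0.74 (adipocyte), and none passed. Dilution is thus argued against by the endothelial list alone and stays open. Read depth as the whole cause is argued against only in part by the thinned counts, where camera still called the list (adjusted p = 3.39e-10), since at full depth that call is lost at adjusted p = 0.26 with an estimated correlation. With the library total as a covariate the difference was 0.371 (SE 0.18), about as large but little more than its error allows, and the 0 genes that rose in that fit leave each single matrix gene open. A change in fibroblasts or in the tissue taken with the tumour may also account for it and was not tested. These bulk counts do not show which cells, tumour cells included, the matrix transcripts came from.

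Foxp3 fell less than the mean of its list, although Gpr83, Tnfrsf18, Tnfrsf9 and Lrrc32 had smaller falls or none. Its log2 CPM relative to the mean of the 10 other tested members was 0.423 higher in the anti-CD4 tumours (exact permutation p = 0.0303), a value that restates the pattern and so leaves a loss of cells with unchanged transcript ratios open. The first version of this test used only the 8 called members, gave 0.736 (exact permutation p = 0.00433), and was replaced because those members had been selected for large falls. Reads from Ccdc22, which did not pass (log2 fold change -0.04, adjusted p = 0.664) and shares 590 exon bases with Foxp3, could make up much of what remained. The Foxp3 level in the anti-CD4 tumours was 0.664 to 1.04 times what this stretch would take from Ccdc22 if reads covered its exons evenly. Coverage need not be even, so this amount is not an upper limit. Shared reads therefore cannot be told apart from a true remainder of Foxp3 transcripts without strand or read positions.

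Loss of plasmacytoid dendritic cells was tested as a hypothesis on members whose values had not been looked at. They were measured in the same tumours as the seen members that prompted it, so a group difference shared by such genes carries over. The same holds for mature dendritic cells below, and neither test is independent evidence. Of 8 tested plasmacytoid members not looked at before, 7 had negative log2 fold changes and 2 fell, Smim5 (-1.03) and Lair1 (-0.72). Tlr7 (-0.06) and Cox6a2 (0.07) were among those that did not pass. The score fell by 0.544 (exact permutation p = 0.0108, adjusted p = 0.0124), while camera with an estimated correlation gave an adjusted p = 0.0915. Fewer such cells could give this fall, and so could lower expression per cell. Whether other cells that express these genes gave part of it was not tested, and the T cell, NK cell and B cell scores fell too. For mature dendritic cells, 2 of 10 such members fell, Il4i1 (-1.28) and Zmynd15 (-0.79), while Cacnb3 (-0.09), Slco5a1 (-0.05), Adcy6 (-0.04), Cd200 (-0.03) and Serpinb6b (0.25) were among those that did not pass. The list median was -0.162, and the score fell by 0.31 (exact permutation p = 0.00216, adjusted p = 0.00433; camera adjusted p = 0.116 with an estimated correlation). Zmynd15 overlaps Cxcl16, a more abundant gene that also fell, over 552 bases on the opposite strand, and without Zmynd15 the score of the other 9 fell by 0.26 (exact permutation p = 0.00866). Fewer cells and lower expression per cell are not separated here either, and a part from other cells was not tested. The members that had been seen first, such as Siglech and Klk1 (-2.15) or Ccl22 and Bcl2l14, gave larger score differences of -1.42 and -1.46.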
